A study of Homo sapiens with 2 samples.

How the data were processed

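Total RNA from Huh7 cells, a human hepatoma cell line, was sequenced as 2 libraries, 1 from cells with a control shRNA and 1 from cells with an shRNA against E2F6. Per the labels' protocols, RNA integrity was checked, the RNA was treated with DNase and libraries were made with an mRNA-seq kit. The authors deposited 1 gene table per library, and per the file headers its values are FPKM, fragments scaled to transcript length and library total. HISAT2 2.0.4, StringTie 1.3.0 and the human build GRCh37 are named per the submitters' processing notes. The role and settings of each tool, the gene annotation release, the read length and whether reads were counted by strand were not given in the sources used here.

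Each table held 21227 rows. In each, 2 rows were dropped, that of TGFB1, which carried no value, and the row after it, which held spilled annotation text, leaving 21225 genes. No gene was at 0 in both libraries. For 23 genes the name had been turned into a date number by spreadsheet software, and the symbol was taken from the gene ID. Of the IDs, 21059 were found in GENCODE release 29 and 20887 in a table of current gene symbols. GENCODE release 29 is built on GRCh38, so it was used only for biotypes, transcript lengths and sequences, overlap between genes and the place of 1 short sequence in E2F6.

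Depth was read from the values. For genes with 1 annotated transcript, FPKM times transcript length came in whole multiples of 1 step, with 98.0% of 5462 values above 0 in the control shRNA library and 98.0% of 5172 in the E2F6 shRNA library within 0.01 of a whole fragment. The step put 1 fragment per kilobase at 0.0583 and 0.0679 FPKM, which implied that the values had been scaled to totals of 17139210 and 14724834. The values do not tell whether these are reads or fragments. Genes with more than 1 transcript made up 72.1% of the annotated genes, and the length the authors used for them could not be recovered. Fragments were therefore estimated with the mean transcript length of GENCODE release 29, and the ratio of the libraries was given an exact conditional binomial 95% interval. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and they are approximate for genes with several transcripts.

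Differences were log2(FPKM + 1) in the E2F6 shRNA library minus that in the control shRNA library. The pseudocount of 1 makes the difference of genes with low values smaller than the log2 ratio, and ratios printed as folds are of the FPKM values themselves. Each group had 1 library, so no test between conditions was possible, and genes were called higher or lower by a rule of size, a difference of at least 1 in size with a mean FPKM of at least 1. Before the data were examined, 37 gene lists with 928 genes were fixed, of which 803 genes were analysed here and 16 stood in more than 1 list. For each of the 30 lists with at least 5 members at a mean FPKM of at least 1, the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 libraries only. By chance 1.5 of 30 lists would lie outside the central 95% if genes varied independently. Members of a list may move together, so more lists may lie outside without any effect of the knockdown.

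Genes to be named were also set by a rule before the data were examined. They were E2F6, the 15 genes with the largest increase and the 15 with the largest decrease among named protein-coding genes with a mean FPKM of at least 5, and the housekeeping reference genes. From each list the rule took the members past the rule of size, or, where none or more than 4 were past it, the 2 highest and the 2 lowest differences at a mean FPKM of at least 1. Any other gene named, as an example of its list or as an overlapping gene, was chosen after its values were seen. Some genes that the rule selects are not reported here.

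The alternatives were a pseudocount of 0.1, no minimum FPKM or a minimum mean of 5, differences centred on the median, quantile normalization, a trimmed-mean (TMM) factor with 30% of the differences and 5% of the levels trimmed at each end, a 1.5-fold threshold, and protein-coding genes alone. After the data were seen, a lowess correction on transcript GC content with a span of 0.3, a filter on the counting interval, and the removal of genes with a processed pseudogene named after them were added. The GC trend was fitted over 9900 protein-coding genes. Every heptamer found in at least 50 genes was then ranked by a rank-sum z, computed over 9717 genes with a 3' UTR of at least 50 bases after correction for GC content and 3' UTR length, and bootstrap intervals came from 2000 draws of genes. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

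The procedures were tested on simulated data made from the mean of both libraries with Poisson counting error. The changed genes and the counting intervals were taken only from genes with a mean of at least 5 FPKM. All 100 genes changed 3-fold and all 100 changed 6-fold passed the rule (100%), as did 6 of 11336 unchanged genes. Recovery of changed genes at lower values, where the pseudocount shrinks differences, was not simulated. Of 5745 counting intervals 96.1% held the true ratio, with fragment numbers known, so errors in transcript length are not covered. Of 100 unshifted lists of 20 genes, 5 fell outside the central 95%. A heptamer given an effect of 0.15 ranked 1, and the lowest z without an effect was -3.59. These simulations hold no variation between cultures, so they say nothing about how far such libraries differ without a knockdown.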

Results

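Gene expression was measured by RNA-seq in Huh7 cells, a human hepatoma line, carrying a control shRNA (1 library) or an shRNA against E2F6 (1 library). E2F6 is a member of the E2F family of transcription factors that lacks the activation domain of the others and represses genes, in part as a member of a polycomb complex. The comparison asked which transcripts differ when E2F6 is knocked down. The control shRNA library listed 20374 of 21225 genes above 0 and the E2F6 shRNA library 19974, with 11705 and 11373 genes at 1 FPKM or more. There were no replicates, so all differences are between these 2 libraries and carry no p-value.

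E2F6 (ENSG00000169016, chromosome 2) was at 2.54 FPKM in the control shRNA library and at 0.997 FPKM in the E2F6 shRNA library, which is 39.3% of the control (95% counting interval 25.8 to 59.3%) and a log2 difference of -0.82. Reads may be divided between E2F6 and the 4 processed pseudogenes named after it. NPPB, which encodes brain natriuretic peptide, was 24.7-fold higher in the E2F6 shRNA library (21.1 to 29.02), and the calcium-binding protein gene S100A9 was 12.9-fold lower (9.67 to 17.5). TAGLN, CNN1, MYL9, FLNC, CYR61 and ANKRD1 were higher. ORM1, ORM2, HAMP, NR1H4 and CEBPA were lower, while HNF4A and GATA6 were higher. By the rule of size, 135 genes were higher and 239 lower among 11574 genes with a mean of at least 1 FPKM, and E2F6 itself stayed short of the rule.

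**Figure D1:**
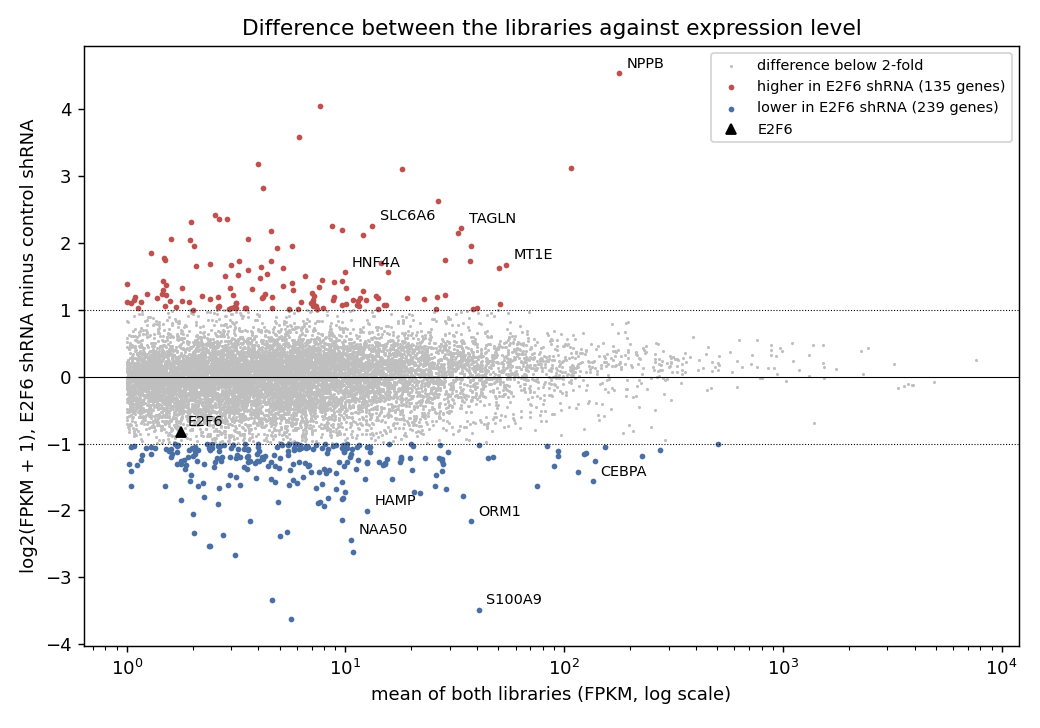
Each point is 1 of the 11574 genes with a mean of at least 1 FPKM, with the mean of both libraries on a log axis in FPKM and the difference in log2(FPKM + 1) on the vertical axis. Red points mark the 135 genes higher and blue points the 239 genes lower in the E2F6 shRNA library by the rule of size, dotted lines lie at differences of 1 and -1, and the triangle marks E2F6 at -0.82.

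Among the 15 largest increases, TAGLN (transgelin) was at 11.4 FPKM in the control and 56.3 FPKM in the E2F6 shRNA library, and values below are given in this order. CNN1 (calponin) was at 2.83 and 16.4 FPKM, the myosin light chain gene MYL9 at 24.2 and 76.8 FPKM, and the actin cross-linker gene FLNC at 6.32 and 22.6 FPKM. CYR61, a matricellular protein gene, was 4.06-fold higher (3.61 to 4.58) and ANKRD1, which encodes a cardiac ankyrin repeat protein, 3.43-fold higher (3.12 to 3.78). The taurine transporter gene SLC6A6 was 5.71-fold higher, the phosphatase gene DUSP3 6.33-fold, the tight junction gene CLDN6 5.47-fold, and the metallothionein gene MT1E 3.26-fold. TGOLN2, a trans-Golgi protein gene, was 5.20-fold higher, MRFAP1 4.69-fold, and TERF2IP, which encodes the telomere protein RAP1, 3.54-fold. C7orf55-LUC7L2 was at 6.71 and 46.2 FPKM, but this is a read-through gene that shares 82.9% of its exon bases with LUC7L2, which was at 12.2 and 6.30 FPKM, so its value is uncertain.

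Among the 15 largest decreases, CCDC117 was 8.31-fold lower (6.58 to 10.6), the N-terminal acetyltransferase gene NAA50 7.10-fold lower (5.43 to 9.37) and AGFG1 5.57-fold lower (4.54 to 6.93). HAMP, which encodes the iron-regulating hormone hepcidin, was at 20.8 and 4.43 FPKM. SAA4, an apolipoprotein of the serum amyloid A family, was at 9.07 and 0.934 FPKM, and SAA2-SAA4, which shares 65.5% of the exon bases of SAA4, was at 3.14 and 1.55 FPKM. The collagen-binding integrin gene ITGA2 was 4.83-fold lower, the glycerol kinase gene GK 4.73-fold, the amino acid transporter genes SLC6A14 and SLC1A5 4.64-fold and 3.55-fold, the forkhead factor gene FOXQ1 4.31-fold and MAGEF1 3.37-fold. ORM1 and ORM2 encode the acute phase protein orosomucoid and are near copies of each other, so the division of reads between them is uncertain. ORM1 was at 62.1 and 13.1 FPKM and ORM2 at 53.9 and 15.01 FPKM.

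**Figure D2:**
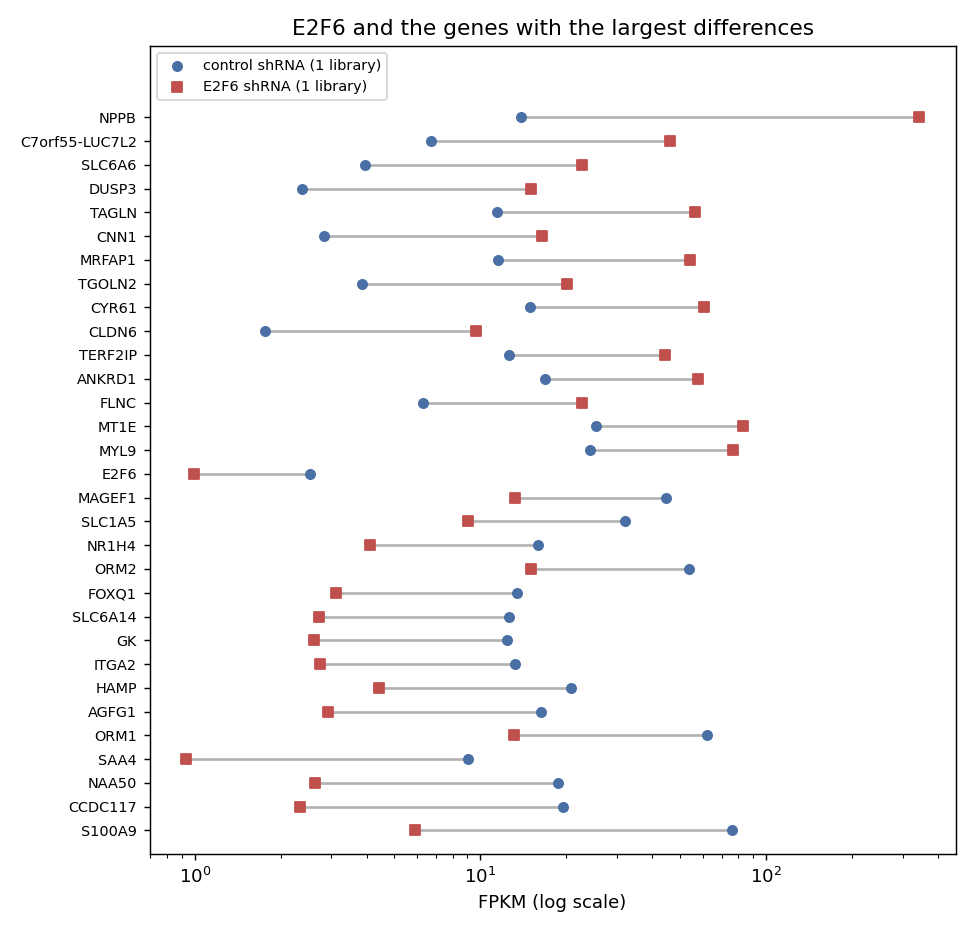
FPKM on a log axis in the control shRNA library (blue circles) and the E2F6 shRNA library (red squares) for E2F6 and the 15 genes with the largest increase and the 15 with the largest decrease, 1 library per group. NPPB went from 13.9 to 342 FPKM and S100A9 from 75.8 to 5.88 FPKM.

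Of 29 hepatocyte secreted protein genes measured, 7 were lower, 0 higher and 22 not past the rule. The list's median difference was -0.52, below all 10000 random lists (percentile 0.0). AHSG (fetuin-A) was at 169 and 61.9 FPKM, APOB at 318 and 138 FPKM and ALB (albumin) at 173 and 77.6 FPKM, while APOE was at 153 and 189 FPKM and TTR (transthyretin) at 74.6 and 91.3 FPKM. The liver transcription factors parted, with 2 higher, 2 lower and 15 of 19 not past the rule. NR1H4, the bile acid receptor FXR, was 3.85-fold lower (3.06 to 4.94) and CEBPA 2.98-fold lower (2.85 to 3.11), whereas HNF4A was 3.36-fold higher (2.85 to 3.96) and GATA6 2.29-fold higher (1.998 to 2.65). In the list of drug metabolism and bile acid genes 1 of 9 was lower, the uptake transporter gene SLCO1B3 at 2.04 and 0.282 FPKM, and the list's median of -0.43 lay at percentile 1.18.

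In the E2F6 polycomb complex list (median -0.08, percentile 21.1) 1 of 16 members was lower, TFDP1, the dimerization partner of the E2F factors, at 21.98 and 8.31 FPKM, and 15 were not past the rule, with RNF2 at 5.91 and 2.99 FPKM and L3MBTL2 at 5.48 and 7.27 FPKM. None of 24 PRC1 and PRC2 subunits passed it (median -0.18, percentile 6.20), PCGF3 having the lowest difference at -0.73 and CBX8 the highest at 0.43. None of 10 other E2F and pocket protein genes passed it either. The values were 48.2 and 68.6 FPKM for E2F1, 3.63 and 6.34 FPKM for E2F4, 10.8 and 6.60 FPKM for RB1 and 4.63 and 2.92 FPKM for RBL1. Germline and meiosis genes, which include textbook E2F6 targets, were mostly below 1 FPKM, with 2 of 17 at a mean of 1 FPKM or more, BRDT at 7.10 and 3.05 FPKM, lower by the rule, and MSH5 at 1.68 and 1.71 FPKM. Chosen after their values were seen, the cohesin gene SMC1B was at 0.0895 and 0.268 FPKM (ratio 2.99, 1.07 to 9.15) and the synaptonemal complex gene SYCE2 at 0.142 and 0.993 FPKM (ratio 6.98, 1.24 to 54.6). The meiotic cohesin gene STAG3 was at 0.0363 and 0.153 FPKM, a ratio whose interval of 0.651 to 275 includes 1, while the piRNA pathway gene PIWIL2 was at 0.749 and 0.327 FPKM (ratio 0.437, 0.233 to 0.805) and the meiosis gene TEX15 at 0.308 and 0.0615 FPKM (ratio 0.2001, 0.0735 to 0.436). Estimated fragments were 6 and 15 for SMC1B, 2 and 10 for SYCE2, 42 and 16 for PIWIL2, and 42 and 7 for TEX15. Of 4 cancer-testis antigen genes at 1 FPKM or more none passed the rule, MAGEB2 being highest at 0.47 and PRAME lowest at -0.24.

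None of 46 G1/S and DNA replication genes passed the rule (median -0.07, percentile 6.90), with RFC2 at 4.85 and 8.38 FPKM and the DNA polymerase alpha gene POLA1 at 8.77 and 5.23 FPKM. Of 40 G2/M and mitosis genes 5 were lower, 0 higher and 35 not past it, the spindle gene ASPM 3.46-fold lower (3.04 to 3.94) and the hyaluronan receptor gene HMMR 3.12-fold lower (2.24 to 4.36), while MYBL2 was at 86.7 and 134 FPKM and UBE2C at 61.7 and 88.7 FPKM. None of 32 DNA damage repair and checkpoint genes passed the rule, yet 24 had a difference below 0 and the median of -0.38 lay at percentile 0.0, with BRCA2 at 2.53 and 0.765 FPKM and RAD54L at 7.77 and 9.73 FPKM. The median GC content of this list's transcripts was 42.1%, and after correction for GC content its median was -0.12 at percentile 4.29, inside the central range. None of 23 p53 target and CDK inhibitor genes passed the rule, BTG2 being highest at 0.78 and CDKN2C lowest at -0.68. Among 21 apoptosis regulators 1 was higher and 1 lower. BIRC2, an inhibitor of apoptosis, was at 3.68 and 1.24 FPKM, and the survival gene BCL2L2 was at 1.47 and 8.31 FPKM. BCL2L2 shares 19.4% of its exon bases with BCL2L2-PABPN1, which was at 6.05 and 4.62 FPKM, so its value is uncertain.

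In the oxidative stress and iron list 5 genes were higher, all metallothioneins, which bind zinc and copper, and 3 were lower, with 20 not past the rule. MT1E was at 25.5 and 83.1 FPKM, MT1F at 8.24 and 19.9 FPKM and MT1H at 0.587 and 2.98 FPKM, and reads may be divided unevenly among these similar genes. The lower ones were HAMP, the cystine transporter gene SLC7A11 at 5.56 and 1.73 FPKM and the aldo-keto reductase gene AKR1B10 at 9.72 and 3.37 FPKM. Of 15 heat shock genes 13 had differences below 0 and 1 was lower by the rule, HSP90AA1 at 129 and 50.7 FPKM, and the median of -0.27 lay at percentile 0.2, below the central range. Hypoxia response genes had a median of -0.28 at percentile 0.910, with 1 of 17 lower and 16 not past the rule, among these BHLHE40 at 31.9 and 15.5 FPKM and PDK1 at 5.85 and 3.27 FPKM. Of 26 unfolded protein and amino acid stress response genes 1 was lower, CALR (calreticulin) at 373 and 174 FPKM.

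In fatty acid synthesis 2 of 19 genes were lower, ACSL3, an acyl-CoA synthetase gene, at 32.6 and 13.5 FPKM and GPAM, the first step of glycerolipid synthesis, at 6.33 and 2.21 FPKM, with the list's median of -0.20 at percentile 1.94. Neither gene passed the rule after correction for GC content (-0.84 and -0.95), and the median came inside the central range under quantile normalization (percentile 5.36) and with a pseudocount of 0.1 (percentile 3.23). None of 23 cholesterol synthesis genes passed the rule, DHCR7 being highest at 0.67 and STARD4 lowest at -0.75. None of 18 fatty acid oxidation genes passed it, SLC25A20 being lowest at -0.84, followed by ACADM at -0.77. None of 20 glycolysis and gluconeogenesis genes passed it, LDHA being at 93.9 and 53.5 FPKM and TPI1 at 200 and 275 FPKM.

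Of 19 immediate early genes 2 were higher and 17 not past the rule, CYR61 and the phosphatase gene DUSP1 at 16.8 and 40.3 FPKM being past it, and the list had a median of 0.35 at percentile 99.97. The TGF-beta, extracellular matrix and EMT list had a median of 0.30 at percentile 99.72, with 1 of 20 members higher, SPARC (osteonectin) at 6.38 and 15.3 FPKM, and 2 lower, among them the cell adhesion gene CDH1 (E-cadherin) at 8.21 and 3.39 FPKM. After correction for GC content this median was 0.19 at percentile 96.82, inside the central range. Of 20 inflammatory NF-kB and acute phase genes 3 were lower, SAA4, the chemokine gene CCL20 at 196 and 80.8 FPKM and SOCS3, an inhibitor of cytokine signalling, at 8.31 and 3.36 FPKM. None of 11 interferon-stimulated genes passed the rule, IFI6 being lowest at -0.70 and OAS3 highest at 0.07. Of 23 Wnt and liver progenitor genes 1 was lower, the R-spondin receptor gene LGR4 at 39.5 and 12.03 FPKM, and of 9 HOX genes 1 was lower, HOXD1 at 2.63 and 0.791 FPKM.

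Ribosomal protein genes had differences above 0 in 34 of 35 cases, none past the rule, with a median of 0.31 at percentile 99.94, RPLP1 being at 142 and 250 FPKM and RPS6 at 285 and 279 FPKM. Reads of genes with processed pseudogenes may be divided with these, so such values are uncertain. EEF1A1P5 was the highest gene of both libraries at 7024 and 8303 FPKM, against 152 and 181 FPKM for EEF1A1. Processed pseudogenes named after the gene numbered 13 for RPS6 and 62 for GAPDH. Of 34 nuclear oxidative phosphorylation genes 1 was lower, NDUFB3 at 39.3 and 15.8 FPKM, and 27 had differences above 0 (median 0.19, percentile 93.9). The 13 mitochondrially encoded genes, none past the rule, had a median of -0.11 at percentile 0.935. This median was 0.00 under quantile normalization, and -0.017 at percentile 7.28, inside the central range, after correction for GC content. None of 12 replication-dependent histone genes passed the rule, HIST1H2AE being highest at 0.56 and HIST1H1C lowest at -0.50. Of 15 housekeeping reference genes none passed it either, the median being 0.16, with GAPDH at 721 and 794 FPKM, ACTB at 283 and 330 FPKM, TBP at 5.02 and 5.31 FPKM, and TFRC, the transferrin receptor gene, lowest at -0.56.

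Of 10 markers each, 4 of fibroblasts and stellate cells, 4 of cholangiocytes, 2 of macrophages, 1 of endothelial cells and 1 of T and B cells had a mean of at least 1 FPKM, and none of these passed the rule. In the fibroblast and stellate cell list COL1A1 was at 20.1 and 36.7 FPKM, COL1A2 at 14.6 and 19.5 FPKM, PDGFRA at 2.502 and 2.42 FPKM and LUM at 3.51 and 2.54 FPKM. The cholangiocyte markers KRT19 and EPCAM were at 82.9 and 122 FPKM and at 19.1 and 13.7 FPKM. LYZ of the macrophage list was at 240 and 133 FPKM. CD68 of that list was at 1.78 and 1.74 FPKM, a value that is uncertain, since it shares 81.7% of its exon bases with a non-coding gene that was at 9.67 and 1.13 FPKM. PECAM1 of the endothelial list was at 1.53 and 2.83 FPKM, and CD3D of the T and B cell list at 9.93 and 7.76 FPKM.

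**Figure D3:**
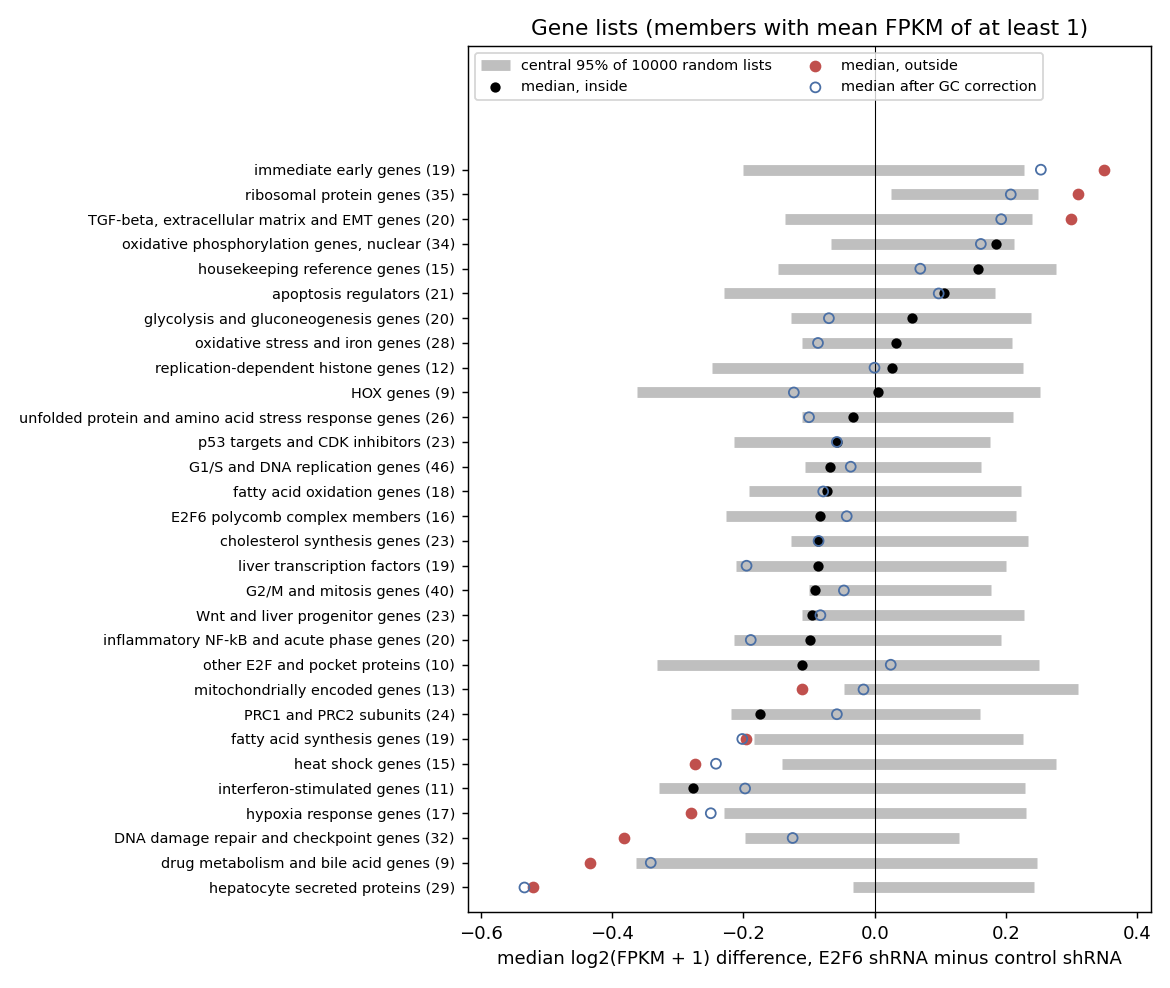
Median difference in log2(FPKM + 1) of each of the 30 gene lists with at least 5 members at a mean of 1 FPKM or more, with the number of such members in brackets, grey bars for the central 95% of 10000 random lists, filled points for the medians (red outside the bar) and open circles for the medians after correction for GC content, to which the grey bars do not apply. Medians lay above the range for 3 lists and below it for 7, hepatocyte secreted proteins being lowest at -0.52.

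Across 9900 protein-coding genes the difference went with the GC content of the transcript (Spearman correlation across genes 0.474, genes not being independent replicates), with a median of -0.43 in the tenth of genes with the lowest GC content and 0.16 in the tenth with the highest. With that trend removed, 114 of the 199 lower and 87 of the 115 higher protein-coding genes kept their call, which BRDT, HMMR, BIRC2, GATA6, SLCO1B3 and CCL20 did not, and 7 of the 10 lists outside the central range stayed outside it.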

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

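The correction for GC content, the filter on the counting interval and the removal of genes with named processed pseudogenes were chosen only after the data were seen. E2F6 was lower under the TMM factor, centring, the GC correction and a pseudocount of 0.1, and with the last its difference of -1.27 passed the rule of size, because a pseudocount of 1 shrinks low values. The counts of 135 higher and 239 lower genes became 269 and 522 with a pseudocount of 0.1, 67 and 128 with a mean of at least 5 FPKM, where fewer genes were tested, and 585 and 1080 with a 1.5-fold threshold. With the GC correction 136 protein-coding genes were lower, against 199 without it. Counts under centring, quantile normalization, the TMM factor, no minimum, protein-coding genes alone, the counting interval and no named pseudogene stayed within 1.5 times. After the GC correction 8 named genes no longer passed the rule (BRDT -0.76, HMMR -0.83, BIRC2 -0.69, GATA6 0.93, SLCO1B3 -0.75, ACSL3 -0.84, GPAM -0.95 and CCL20 -0.80), and BRDT also fell short after centring. The medians of DNA repair (-0.12), TGF-beta (0.19) and mitochondrially encoded genes (-0.017) came inside the central range after the GC correction, and those of liver transcription factors (-0.20), the unfolded protein response (-0.10) and inflammatory genes (-0.19) moved below it. A mean of at least 5 FPKM put DNA repair (-0.20) and TGF-beta (0.19) inside, and the unfolded protein response (-0.24) and inflammatory genes (-0.49) below. Quantile normalization, which moved the median of all expressed genes by 0.03, put mitochondrially encoded (0.00) and fatty acid synthesis genes (-0.15) inside, G2/M genes (-0.12) below and oxidative phosphorylation (0.18) above. Fatty acid synthesis was also inside with a pseudocount of 0.1 (-0.20). The cause was not tested for these lists. No median outside the central range changed sign, but those of the glycolysis, oxidative stress, HOX, histone, E2F, polycomb complex, p53 and Wnt lists, inside it, did under the GC correction, quantile normalization or the higher minimum. Counts were not run, as the tables hold FPKM alone. No paired analysis was possible because each group has 1 library. With 1 fragment per kilobase at 0.0583 and 0.0679 FPKM, genes near that level are not resolved.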

Other observations

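The tests of GC bias as the whole cause, of 3' UTR composition and of fibroblast or stellate cells, the 3 gene lists next described and the scans of coding sequences and 5' UTRs were chosen only after the results were seen. Of 48 YAP and SRF target genes at a mean of 1 FPKM or more, 11 were higher, 0 lower and 37 not past the rule, with a median difference of 0.59. They included the cardiac actin gene ACTC1 (0.115 and 4.96 FPKM), the skeletal actin gene ACTA1 (0.245 and 3.83 FPKM), the kinase gene NUAK2 (1.73 and 5.74 FPKM) and SRF itself (12.4 and 24.0 FPKM, not past the rule). Of 8 metallothionein genes 6 were higher, with a median of 1.15, MT1M being at 7.37 and 23.8 FPKM and MT2A, not past the rule, at 22.6 and 44.9 FPKM, and of the 4 members that were not noted before the list was written 2 were higher (median 0.98). Of 20 liver genes regulated by C/EBP alpha or FXR, 11 were lower and 0 higher (median -1.11), among them the organic solute transporter gene SLC51B (14.9 and 4.33 FPKM), HABP2 (9.48 and 2.47 FPKM) and the kininogen gene KNG1 (5.88 and 2.17 FPKM), and the 9 members that were not noted before the list was written had a median of -0.43 at percentile 0.320 with 2 of them lower, but of -0.28, inside the central range, at a mean of at least 5 FPKM.

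The median of the YAP and SRF target genes lay above the random lists, although 37 of 48 members were not past the rule and the list was written because some of its members were among the largest increases. A GC bias of the libraries, so far as the fitted trend captures it, is argued against. After GC correction the list's median lay at percentile 100 of the random lists. That median includes members picked for their large increases. The 38 members not noted before the list was written also lay at percentile 100 after GC correction, with a median of 0.40. Fibroblast or stellate cells in the culture cannot be told apart from a change within Huh7 cells, because their markers moved apart. The gain of COL1A1 was 36.8% of that of TAGLN (28.7 to 45.1), that of COL1A2 11% and that of COL3A1 1.73%. LUM went from 3.51 to 2.54 FPKM (ratio 0.723, 0.518 to 1.01), with a difference of 0.09 after GC correction. DCN, the other marker set for this test, was not among the genes listed. COL1A1 and COL1A2 were already at 20.1 and 14.6 FPKM in the control. The 38 members that were not noted before the list was written had a median of 0.38, at percentile 100, with 3 of them higher. This goes with a shift of the group as a whole. The list was written after the fixed lists had been scored, however, so these members are not an unseen set and their percentile is weak evidence. Loss of E2F6 may lie behind this shift. With 1 culture per group, a difference in cell density or handling and an effect of the shRNA on other transcripts are as open. None of these was tested.

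Genes lower in the E2F6 shRNA library were poorer in G and C (median 41.7%) than those that were higher (54.1%). Transcript length as the whole cause is argued against. Within 5 groups of like length the correlation of GC content with the difference had a median of 0.468. The correlation rose with length, from 0.246 in the group of shortest transcripts to 0.597 in that of the longest. The fitted GC trend as the whole cause of the genes past 2-fold is argued against as well. Of the 314 protein-coding genes, 64.0% kept their call after the correction. The correction shifts genes of like GC content alike, so GC effects that differ between such genes are not covered. For the trend itself a GC bias of the libraries may be the source, as in 622 long non-coding genes the rise per 10 percentage points of GC was 0.133, which is 0.648 of that in protein-coding genes (bootstrap interval 0.431 to 0.882). An effect of the knockdown on AU-rich transcripts would give the same trend and stays open, untested.

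The 1148 genes with the heptamer GCTGGTT in the 3' UTR were lower than the other 8569, with medians of -0.07 and 0.01 after correction for GC content and 3' UTR length, and its rank-sum z of -8.81 was the lowest of 16132 heptamers, followed by -6.36 for ATCAACA. The other 139 heptamers made of the same letters had a median z of 0.274 (bootstrap interval -0.0208 to 0.534), against 0.171 over all ranked heptamers. GC content and 3' UTR length had been corrected before any z was computed, so this median says little about base composition or length. Genes with GCTGGTT stayed lower after that correction, which argues against these trends, as fitted, as the whole cause. GCTGGTT was held by 50 of 191 lower genes, against 22.3 (14 to 31) in random genes of like 3' UTR, and by 12 of 102 higher genes. Of the 15 largest decreases 5 held it (NAA50, AGFG1, HAMP, SLC1A5 and MAGEF1). It had been picked because genes that hold it were lower, so these counts are no separate evidence. Seed pairing of an shRNA in the E2F6 shRNA library is a candidate explanation that the comparison of sites left open. Genes with the heptamer in the 3' UTR only had a median of -0.067 (bootstrap interval -0.092 to -0.040). The median was -0.064 (-0.085 to -0.044) with it in the coding sequence only and 0.021 (0.014 to 0.030) with it in neither part. The first 2 groups cannot be told apart (difference -0.0037, bootstrap interval -0.0337 to 0.0311), and both lay below the last. No group was corrected for length or GC content of the coding sequence, so the comparison does not separate the site from these traits. In the scan of coding sequences, which had that correction, the 1114 genes with the heptamer had a median of -0.039. There ATCAACA ranked 1 of 16372 heptamers and GCTGGTT 2, and in 5' UTRs GCTGGTT ranked 9192 of 13793. ATCAACA is absent from the E2F6 transcript. Its reverse complement was not searched there, so this absence does not bear on pairing by the other strand of a hairpin. E2F6 holds it once (chromosome 2, 11453755 to 11453761 on GRCh38, coding in 2 transcripts and UTR in 2 others), but 18.4% of the ranked heptamers occur in E2F6, and the hairpin's sequence was not given in the sources used here.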
